A study of Homo sapiens with 8 samples.

How the data were processed

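Extracellular vesicles from human brain tissue of 8 regions were profiled by small RNA sequencing, with 1 library per region and no replicates. Per the labels, RNA was purified with column kits and made into libraries with the D-Plex small RNA kit, in which RNA ends are tailed and copied by template switching, so that fragments of longer RNAs are captured beside miRNAs. The deposited table held 8 columns of whole-number counts, and each column was joined to its region through the description field of the labels, with 0 columns left over. The submitters' processing notes name the human genome build hg38, cutadapt 1.18, Bowtie and Picard. The order in which RNA classes were counted, the mismatches allowed, and the handling of molecular tags and duplicates are not given in the sources used here.

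The authors' counts were given for 2656 mature miRNA names, 1917 miRNA hairpins, 20288 gene symbols, 15767 lncRNA names and 203835 transcript identifiers, and as totals for 9 classes that have no members of their own. These 9 were rRNA, tRNA, Y RNA, vault RNA, 7S RNA, U RNA, small nucleolar RNA, mitochondrial RNA, and introns with intergenic sequence. Lists drawn up for the members of the Y, vault and 7S RNAs and for the neuronal RNA BC200 therefore gave no member values, and only the class totals of the first 3 are reported. Of the counts on gene symbols, 99.2% fell on names that GENCODE 44 calls protein coding, directly or through synonyms in the RefSeq table. Loci are from GENCODE 44 on GRCh38.

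Library depth was the sum of all deposited counts. Shares of a class carry exact Clopper-Pearson 95% intervals. Counts of miRNAs, genes and lncRNAs were scaled to CPM, counts-per-million of their own class, after 0.5 was added for log2 ratios, and carry exact Poisson 95% intervals. A count of 0 was read as compatible with up to 3 counts. Intervals and such floors cover counting error only, because reads are not known to be independent molecules. Between-library spread could be gauged only from the 3 neocortical gyri, which are different regions and no replicates.

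No test between regions was possible with 1 library each. A feature was set apart in a region by a size rule. Its value lay at least 2-fold from the median of the other 7 libraries, outside their range, and its Poisson interval excluded that median. Features with a mean count of at least 50 were used. The rule was tested on simulated data with known changes. With counting noise alone it recovered 40.0% to 50.0% of 2-fold and 100.0% of 4-fold changes. With 20% spread between libraries added, it set apart 18 of 76 unchanged miRNAs and 182 of 8684 unchanged genes in the thalamus, and 6 of 75 miRNAs and 53 of 8663 genes in the deeper cerebellum.

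Lists were fixed before the data were examined. The 14 miRNA lists were oligodendrocyte, neuronal, astrocyte, microglia and leukocyte, vascular, erythroid, ciliated and choroid plexus, HOX cluster, 14q32 cluster, let-7 family, miR-17/92 family, cerebellum-high and cerebellum-low miRNAs of rodent surveys, and liver and muscle miRNAs. The 14 lists of longer RNAs were telencephalic neuron, neuronal, cerebellar neuron, thalamic, hindbrain HOX and brainstem, oligodendrocyte, astrocyte, microglia, vascular, haemoglobin, choroid plexus, liver, mitochondrial mRNA and nuclear long RNA names. A list's value was the median log2 ratio of its measured members to the median of the other 7 libraries. Where under 50% of the members of a longer RNA list had a mean count of 50, a mean of 20 was used instead. Counting intervals of list medians came from 200 Poisson resamples, and percentiles from 10000 random lists matched on mean expression in 10 bins. The percentiles describe these libraries and are no tests.

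Named features followed a rule set before the data were examined. It took the 10 most abundant miRNAs, up to 3 miRNAs set apart upward and up to 2 downward in each region by ratio, up to 3 genes set apart upward in each region, up to 4 of the most abundant members of each list, and the 3 most abundant lncRNAs by mean count, with clone names passed over. Some list members counted in the lists are not reported singly here, other members are named as examples, and any further name is said to have been chosen after its values were seen.

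Spearman correlations over features described the 28 pairs of libraries, with principal components. Across libraries, 3 relations between miRNA and mRNA lists of the same cell type were tested with Pearson's r and Spearman's rho, two-sided exact permutation tests of the pairings, and Benjamini-Hochberg adjustment over the 3. Alternatives were trimmed mean of M values (edgeR 4.0.16) and median-of-ratios factors (DESeq2 1.42.0) as scalings only, the all-count scale (counts divided by library depth), a mean count of 10 or no filter, 2 added counts, stricter size rules, the gyri as reference, list means, class shares without rRNA, without the most abundant feature of each library, or over features with a mean count of at least 10, a mean count of 500 for similarity, and leaving out each library in turn. Thinning the cerebellum counts and filters on mean CPM were added after seeing the data. Computation used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, matplotlib 3.10.9 and R 4.3.3. Genes of chromosome Y and lncRNAs used to infer sex are not reported for any library.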

Results

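Vesicles that cells release into the space between them were collected from human brain tissue of 8 regions, and their small RNA was sequenced to compare the regions, with 1 library per region. The regions were the orbitofrontal, postcentral and occipital gyri of the neocortex, the hippocampus, the thalamus, the medulla, the corpus callosum and the cerebellum. The labels do not say whether the tissue came from 1 brain. Depth lay between 21277699 counts in the occipital gyrus and 34502550 in the postcentral gyrus, apart from 121334177 in the cerebellum, 4.94 times the median of the other 7. Mature miRNAs took 11986 counts in the corpus callosum to 27659 in the occipital gyrus, and 363241 in the cerebellum, which held 72.8% of all miRNA counts. Gene symbols, read here as fragments of mRNA without a test of this, took 813107 counts in the thalamus to 2583851 in the orbitofrontal gyrus, and 16456521 in the cerebellum. In CPM (counts-per-million of the class total), 3 miRNA counts amounted to 8.26 in the cerebellum and 250.3 in the corpus callosum, and 3 gene counts to 0.182 and 2.59. With no replicates, the 3 gyri gave the only gauge of spread between libraries. The median gene differed 1.42-fold over the gyri and 12.4% of 8488 genes differed at least 2-fold, while the median miRNA differed 1.89-fold and 39.8% of 108 at least 2-fold. These figures include counting error, which is large for miRNAs with few counts in the gyri. An example is miR-379-5p, with 4, 5 and 7 counts in the orbitofrontal, postcentral and occipital libraries. Values below are higher or lower by size only and on the CPM scale, and signs that differ on the all-count scale (counts divided by the depth of the library) are given for the list values printed and for features described as set apart. No difference between regions was tested, and intervals are 95% counting intervals.

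Ribosomal RNA made up most of every library, and tRNA was the class that differed most between regions. The rRNA share was lowest in the cerebellum, at 67.5%, and highest in the thalamus, at 89.7%. Transfer RNA was 0.0749% (0.0738% to 0.0761%) of the orbitofrontal library and 2.99% (2.985% to 2.998%) of the medulla library, a 39.9-fold range. Y RNA, a small RNA bound by Ro protein, was 0.0794% in the orbitofrontal gyrus and 1.43% in the medulla, an 18.0-fold range that was 5.46-fold without the orbitofrontal library. Vault RNA ranged 8.01-fold, from 0.0146% in the hippocampus to 0.117% in the medulla. Without the medulla library tRNA ranged 23.8-fold and vault RNA 4.72-fold. Introns with intergenic sequence took 14.1% of the orbitofrontal library and 11.7% of the cerebellum library, against 2.21% in the thalamus. The miRNA share was 0.0507% in the thalamus and 0.299% in the cerebellum, a 5.9-fold range, and miRNA hairpins ranged 5.17-fold from 0.0151% to 0.0778% in the same libraries. Gene symbols ranged 4.4-fold from 3.08% in the thalamus to 13.6% in the cerebellum, lncRNA 3.63-fold, transcript identifiers 4.41-fold and small nucleolar RNA 4.79-fold between the same libraries. Without the cerebellum library the ranges were 2.56-fold for miRNA, 2.52-fold for miRNA hairpins and 2.02-fold for small nucleolar RNA. The U RNA share ranged 2.6-fold, 7S RNA 1.76-fold, from 0.23% in the cerebellum to 0.403% in the occipital gyrus, and mitochondrial RNA 1.56-fold, from 1.53% in the thalamus to 2.38% in the medulla. Among the 3 gyri, tRNA ranged 23.8-fold and Y RNA 12.4-fold, in both through the low orbitofrontal library, and the postcentral and occipital gyri differed 5.1-fold and 3.1-fold. With rRNA left out of the total, tRNA ranged 76.0-fold and Y RNA 34.2-fold, both from the orbitofrontal gyrus to the medulla. The miRNA share then ranged 4.13-fold, from 0.223% in the orbitofrontal gyrus to 0.92% in the cerebellum, and lncRNA 1.25-fold. Mitochondrial RNA ranged 2.17-fold, lowest in the cerebellum and highest in the thalamus, and was 0.976 times as high in the medulla as in the thalamus.

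**Figure D1:**
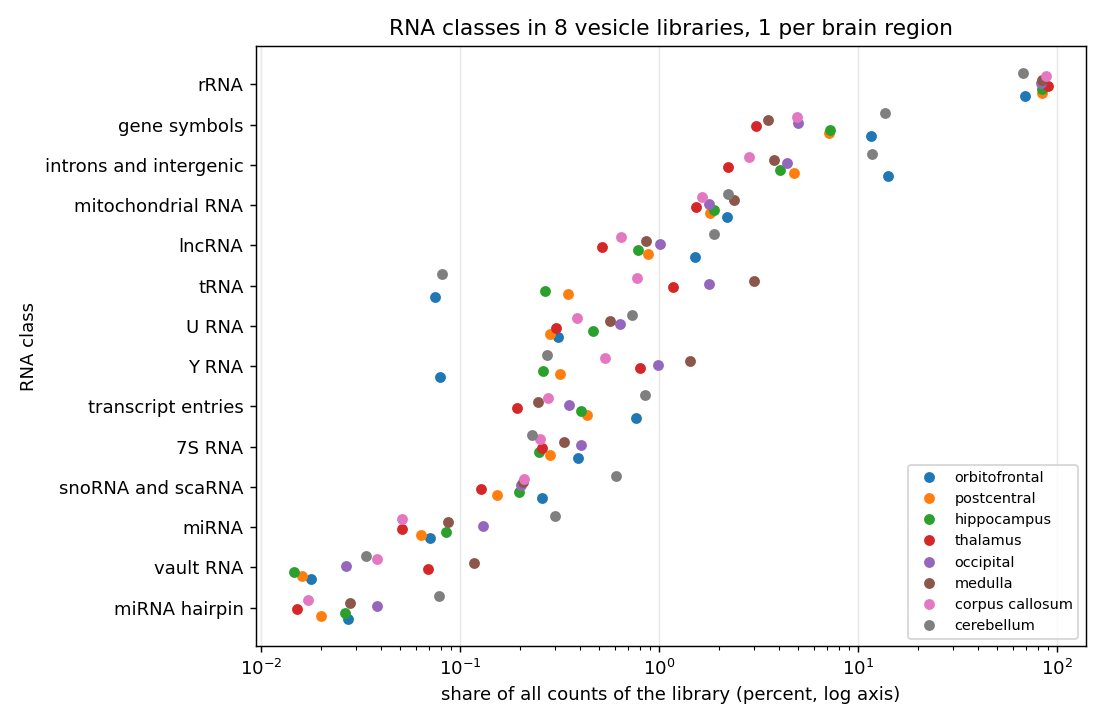
Share of each RNA class in all counts of each library, in percent on a log axis, with 1 point per region. Transfer RNA reaches from 0.0749% in the orbitofrontal gyrus to 2.99% in the medulla, and introns with intergenic sequence from 2.21% in the thalamus to 14.1% in the orbitofrontal gyrus.

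Messenger RNA fragments of telencephalic neurons, which belong to cortex and hippocampus, were about as high in the 3 gyri, the hippocampus and the library labelled corpus callosum, and low in the thalamus, medulla and cerebellum. Over 17 measured genes, the median log2 ratio to the other 7 libraries was -3.21 (-3.75 to -2.81) in the thalamus, -3.20 (-3.59 to -2.64) in the medulla and -3.88 (-4.29 to -3.51) in the cerebellum, each below all 10000 random lists (percentile 0). It was 0.31, 0.42 and 0.38 in the orbitofrontal gyrus, postcentral gyrus and hippocampus, and -0.11 in the occipital gyrus. In the cerebellum, 10 of the 17 were set apart lower, among them NRGN, a calmodulin-binding protein of forebrain neurons (chromosome 11, 124739942 to 124747210), at 4.13 CPM (3.21 to 5.24) against 1276 to 2160 in the gyri. NEUROD2, which granule cells also express, was set apart higher there, 2.13-fold. CAMK2A and ENC1 were set apart higher in the orbitofrontal gyrus, 2.11-fold and 2.27-fold. The ratios in the gyri and hippocampus hinge on which libraries form the median: without the postcentral, hippocampus or corpus callosum library the orbitofrontal value was 1.6, and 1.32 without the occipital library. The postcentral value was then 1.02 (without the occipital library) to 1.31 (without the orbitofrontal or corpus callosum library, and 1.26 without the hippocampus), and the hippocampus value 1.25 (without the occipital library) to 1.57 (without the orbitofrontal or postcentral library, and 1.41 without the corpus callosum). Without the thalamus or medulla library the 3 values were 0.25, 0.188 and 0.242, and without the cerebellum 0.472, 0.188 and 0.298. The occipital value turned to 0.439 without the orbitofrontal, hippocampus or corpus callosum library and to 0.429 without the postcentral library.

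Fragments of cerebellar neuron genes were highest in the cerebellum, with 17 of 18 measured members set apart higher and a median log2 ratio of 4.36 (4.18 to 4.68, percentile 100). ZIC1, a zinc finger factor of granule cell precursors (chromosome 3, 147393422 to 147510293), stood at 1721 CPM (1701 to 1741) there and at 164.8 in the thalamus, its next highest library. NEUROD1, a granule neuron factor, was at 532.0 (520.9 to 543.3) against 5.65 to 14.95 elsewhere, GABRA6, a granule cell GABA receptor subunit, at 135.6 against 0.498 to 3.69, and CALB1, a calcium-binding protein of Purkinje cells, 17.5-fold higher. ITPR1, also of Purkinje cells, was the member not set apart in the cerebellum, 1.05-fold lower (log2 1.25 higher on the all-count scale), and it was set apart lower in the medulla. The same list had a median of 0.95 in the thalamus and 0.61 in the medulla, the latter turning to -0.226 on the all-count scale. It was -0.0244 (0.989 on the all-count scale), -0.234, -0.561, -0.226 and -0.436 in the orbitofrontal, postcentral, hippocampus, occipital and corpus callosum libraries, and the postcentral value was 0.0355 without the cerebellum library.

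Thalamic genes were highest in the thalamus, with a median log2 ratio of 2.63 (2.29 to 2.95, percentile 100) over 7 measured genes, 4 of them set apart higher. TCF7L2, a transcription factor of thalamic neurons (chromosome 10, 112950247 to 113167678), was at 1277 CPM (1200.0 to 1357) against 38.5 to 67.8 elsewhere. The list's SLC17A6, a vesicular glutamate transporter, was 6.18-fold higher, CALB2 7.52-fold and NTNG1 7.45-fold, and medulla stood next with 126.7 for SLC17A6 and 191.8 for CALB2. SHOX2, under the mean of 50 counts, was at 184.5 (156.1 to 216.5) in the thalamus and at most 27.9 elsewhere. Of the members below the median of the others in the thalamus, LHX2 was at a log2 ratio of -3.16 on 3 counts, or 3.69 CPM (0.761 to 10.8) against 0.547 to 49.3 elsewhere, and PRKCD was 2.5-fold lower. RORA was set apart higher in the cerebellum, 4.51-fold. The mean over members in the thalamus was 1.39. The list's medians elsewhere ran from -0.524 in the cerebellum to 0.34 in the orbitofrontal gyrus, and on the all-count scale those of the cerebellum, occipital gyrus and medulla changed sign, to 0.616, -0.481 and -1.0.

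Genes of the hindbrain were highest in the medulla but rested on few counts. Of 23 listed hindbrain HOX and brainstem genes only HOXB7 and SLC6A5 reached a mean count of 20. Their median log2 ratio was 2.52 (1.87 to 3.19) in the medulla, midway between 0.103 for HOXB7 and 4.94 for SLC6A5. It was 1.8 (0.724 to 2.55) in the occipital gyrus, 1.38 (-0.0566 to 2.08) in the thalamus and -1.74 to 0.0461 in the other 5, where the signs of the hippocampus and corpus callosum changed on the all-count scale. On that scale the occipital gyrus, at 1.77, stood above the medulla, at 1.64. SLC6A5, the glycine transporter of inhibitory brainstem neurons, was at 91.8 CPM (72.7 to 114.5) there, at 28.3 in the cerebellum and at 1.55 to 3.77 in the other 6. All 16 HOX genes together were at 253.4 CPM (220.9 to 289.4) in the medulla, 192.0 (166.6 to 220.3) in the occipital gyrus, 93.5 in the thalamus and 13.2 to 36.2 in the other 5, and 12 of the 16 had their highest value in the medulla, such as HOXB5 (chromosome 17, 48591257 to 48593779) at 33.7 (22.6 to 48.4). On the all-count scale the sum was higher in the occipital gyrus, at 204 of 21277699 counts, than in the medulla, at 218 of 24551584. HOXB6, HOXB7, HOXC5 and HOXC6 were highest in the occipital gyrus, where HOXB7 was at 135.6 against 73.8 in the thalamus and 16.3 in the medulla.

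**Figure D2:**
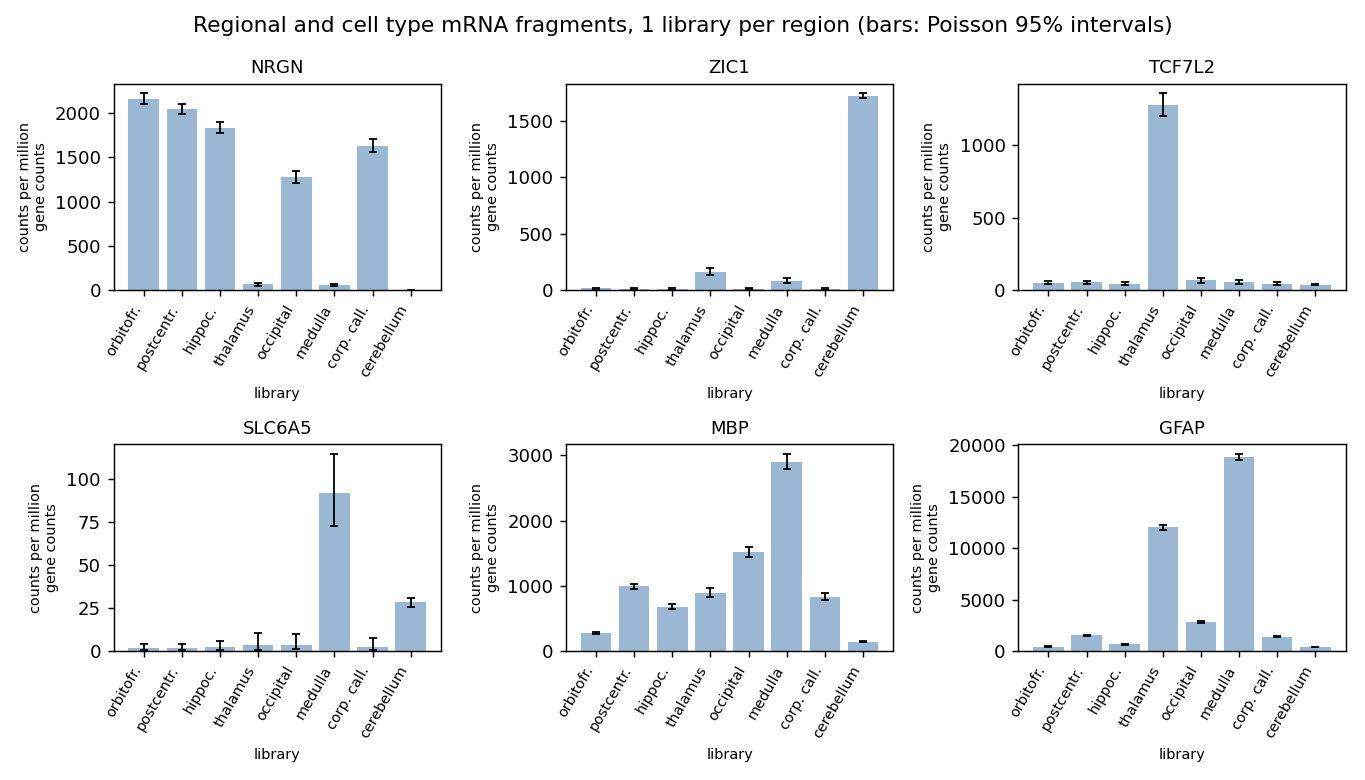
CPM of 6 genes in each library, with bars for the value and whiskers for exact Poisson 95% intervals (counting error only). NRGN is low in the thalamus, medulla and cerebellum, ZIC1 high in the cerebellum, TCF7L2 in the thalamus and SLC6A5 in the medulla, and MBP and GFAP are highest in the medulla.

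Oligodendrocyte, astrocyte and microglia genes were highest in the medulla, relative to all gene counts, and oligodendrocyte and microglia genes were lowest in the cerebellum. Of 19 measured oligodendrocyte genes, 16 were set apart higher in the medulla and 15 lower in the cerebellum, with median log2 ratios of 1.5 (1.43 to 1.64) and -2.33 (-2.44 to -2.22). MBP, a basic protein of the myelin sheath, was at 2902 CPM in the medulla and 142.6 in the cerebellum, 3.47-fold higher and 6.27-fold lower than the median of the others. MOBP was 4.01-fold higher in the medulla and 8.55-fold lower in the cerebellum. SEPT4, also an oligodendrocyte gene, was set apart higher in the cerebellum, 2.89-fold. The list was at -1.46 (-1.69 to -1.27) in the orbitofrontal gyrus and 0.18, -0.43, 0.41 and 0.46 in the postcentral gyrus, hippocampus, thalamus and occipital gyrus, and those of hippocampus and thalamus turned to 0.254 and -0.63 on the all-count scale. The postcentral value was -0.0087 without the cerebellum library.

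Of 19 astrocyte genes, 9 were set apart higher in the medulla, where the median log2 ratio was 1.25 (1.03 to 1.37). On the all-count scale the medulla value was 0.132, and the postcentral gyrus was highest, at 0.694. GFAP, the intermediate filament of astrocytes (chromosome 17, 44903159 to 44916937), was at 18840 CPM in the medulla and 12030 in the thalamus against 395.6 to 2836 elsewhere, and CD44, an adhesion molecule of fibrous astrocytes, was set apart higher in the medulla, at 243.0 against 8.51 to 201.7 elsewhere. The glutamate transporter SLC1A2 was in contrast lower in the thalamus by 4.69-fold (set apart) and in the medulla by 2.35-fold. SPARCL1 and AQP4, the astrocyte water channel, were set apart higher in the postcentral gyrus, 2.43-fold and 2.2-fold. The astrocyte list was at -0.776, 0.637, -0.357, 0.768, 0.325, -0.346 and -0.964 in the orbitofrontal, postcentral, hippocampus, thalamus, occipital, corpus callosum and cerebellum libraries, and those of the orbitofrontal gyrus, thalamus, occipital gyrus and cerebellum turned to 0.412, -0.534, -0.204 and 0.336 on the all-count scale. The lowest library depended on the summary, since the mean over members was -0.931 in the orbitofrontal gyrus and -0.8 in the cerebellum, with 6 and 4 genes set apart lower. Without the orbitofrontal or cerebellum library the occipital value was -0.000893.

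Among 10 measured microglia genes, 8 were set apart higher in the medulla, where the median log2 ratio was 1.64, and 5 lower in the cerebellum, at -1.45 (-1.63 to -1.19). On the all-count scale the cerebellum value was -0.126, and the thalamus was lowest. CD74, a chaperone of antigen presentation, was 4.9-fold higher in the medulla, SPP1 4.68-fold and P2RY12, a receptor of resting microglia, 2.92-fold. The list stood at -0.715 in the orbitofrontal gyrus and 0.762 in the thalamus, turning to 0.345 and -0.459 on the all-count scale, and at -0.344, -0.323, 0.558 and 0.141 (-0.29 on the all-count scale) in the postcentral gyrus, hippocampus, occipital gyrus and corpus callosum. The 13 vascular genes had a median of -1.05 in the cerebellum, which turned to 0.168 on the all-count scale, with 7 set apart lower, such as VWF of endothelium, 10.6-fold. VWF was set apart higher in the occipital gyrus, 2.86-fold, where the list was at 0.51, and elsewhere the list lay between -0.18 and 0.363, all 6 of these changing sign on the all-count scale. Haemoglobin list genes, 4 of them measured, were at 1.92 (1.23 to 2.11) in the medulla and -1.76 (-2.18 to -1.16) in the orbitofrontal gyrus, and at -1.22, 1.01, 0.61, 1.09, -0.894 and -1.27 in the postcentral, hippocampus, thalamus, occipital, corpus callosum and cerebellum libraries. The value of the thalamus turned to -0.867 and that of the cerebellum to 0.255 on the all-count scale, and that of the corpus callosum was -0.287 to -0.298 without the hippocampus, occipital or medulla library. Of the medulla counts, 87 were on HBA1 and 35 on HBB.

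Choroid plexus genes, which mark the tissue that makes cerebrospinal fluid, were highest in the medulla, with a median log2 ratio of 3.43 over 3 measured genes, and stood at 1.83 in the thalamus and 1.64 in the cerebellum. The cerebellum value was -0.00234 with no count filter, and on the all-count scale it was 2.86, above the 2.74 of the medulla. TTR, the transthyretin of choroid plexus and liver, was at 223.2 CPM (192.7 to 257.1) in the medulla, 24.6 in the thalamus, 7.78 in the cerebellum and 0 to 1.73 in the other 5. AQP1, a water channel, was set apart higher in the medulla, 10.8-fold, and TRPM3, a channel that neurons also express, in the cerebellum, 3.11-fold. TTR was the only measured member of the liver list, at a log2 ratio of 7.0 in the medulla, and all 9 liver genes held 219 counts there, 192 of them on TTR. The choroid plexus list was at -1.87, -1.09, -1.10, 0.342 and 0.205 in the orbitofrontal, postcentral, hippocampus, occipital and corpus callosum libraries, the last turning to -0.775 without the orbitofrontal, postcentral or occipital library and -0.383 without the hippocampus library, and to -0.855 on the all-count scale. The occipital value was -0.0252 without the orbitofrontal, hippocampus or corpus callosum library and -0.272 as a mean over members. Neuronal genes shared by all regions had medians over 32 genes of 0.10, 0.29, 0.13, -0.353, -0.0858, -0.524 and 0.13 in the orbitofrontal, postcentral, hippocampus, thalamus, occipital, medulla and corpus callosum libraries, and -0.68 in the cerebellum, the last pair turning to -0.456 and 0.671 on the all-count scale. Of these 32 genes, 2 were set apart higher and 8 lower in the cerebellum, 2 and 4 in the thalamus and 1 and 5 in the medulla. The neurofilament gene NEFH was set apart higher in the medulla, 7.76-fold, NEFM in the thalamus, 2.66-fold, and the synaptic gene SNAP25 in the cerebellum, 2.09-fold. Mitochondrial mRNAs, 4 of 13 measured and 5 at 0 in every library, had medians of -0.811 in the corpus callosum to 0.719 in the medulla, the latter turning to -0.473 on the all-count scale, as the postcentral value of -0.209 did to 0.116.

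**Figure D3:**
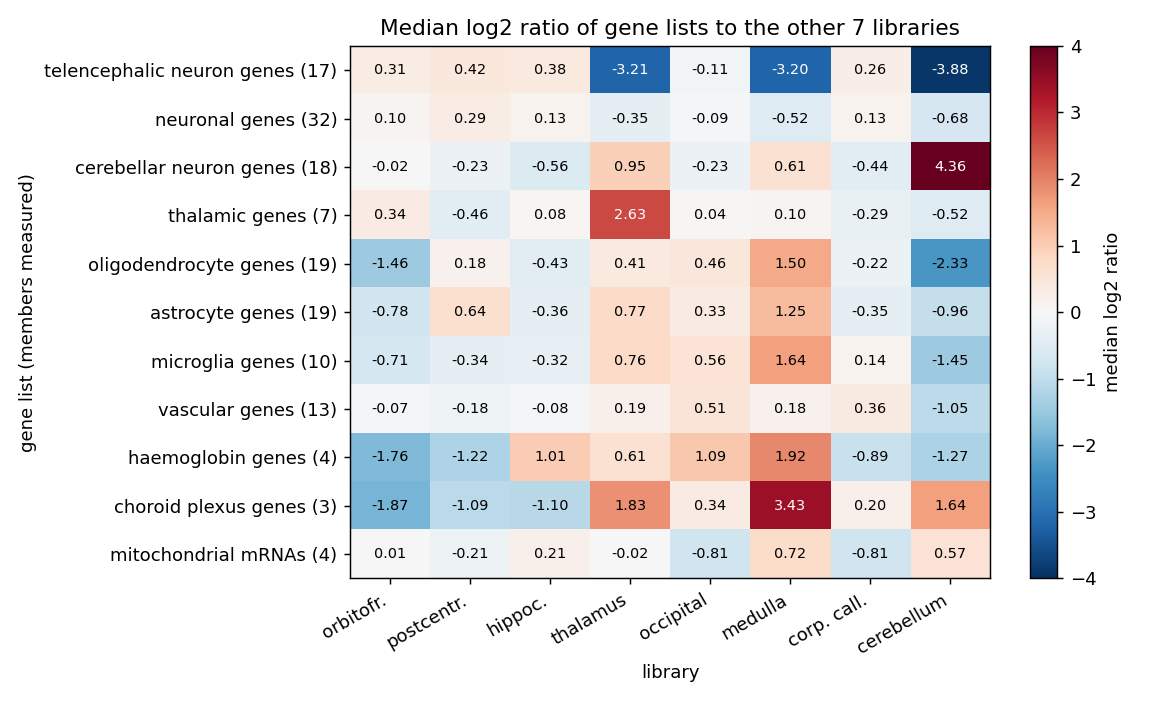
Median log2 ratio of each gene list (vertical axis, with its number of measured members) in each library (horizontal axis) to the median of the other 7, on the CPM scale. Cerebellar neuron genes reach 4.36 in the cerebellum and thalamic genes 2.63 in the thalamus, while several glial, vascular and haemoglobin values change sign on the all-count scale, such as astrocyte genes in the cerebellum from -0.964 to 0.336.

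The library labelled corpus callosum, a tract of white matter, held neuronal and glial fragments at levels close to those of the gyri. Its 17 telencephalic neuron genes were 0.988 times (0.915 to 1.06) their median in the 3 gyri, and NRGN was at 1628 CPM (1555 to 1703). Against the other 7 libraries their median log2 ratio was 0.26 (0.11 to 0.38), with NEUROD6 of cortical projection neurons set apart higher, 3.77-fold. Oligodendrocyte genes lay within the range of the gyri, at -0.25 (-0.347 to -0.17) against the median of the gyri. The gyri themselves ran from -1.7 (orbitofrontal) to 0.259 (occipital) on that measure. Against the other 7 libraries these genes were at -0.22 (-0.295 to -0.112), with 0 of 19 set apart, MBP 1.07-fold and MOBP 1.13-fold lower. The telencephalic ratio to the other libraries was 1.09 without the orbitofrontal, postcentral or occipital library, 1.04 without the hippocampus, 0.0843 without the thalamus or medulla and 0.0915 without the cerebellum. The oligodendrocyte ratio was then -0.35 without the orbitofrontal and -0.0856 without the occipital or medulla library.

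Over all 8488 genes, the cerebellum and medulla had the most genes set apart. In the cerebellum 733 genes were higher and 1074 lower, and ZIC1, ZIC4 and GABRA6 had the largest ratios. In the medulla 494 were higher and 397 lower, led by SLC6A5, by DAO, an enzyme of hindbrain astrocytes, at 61.6 against 0 to 35.7 elsewhere, and by GFAP. The thalamus had 222 higher and 271 lower, led by RGS16, a regulator of G protein signalling, at 461.2 (415.7 to 510.3) against 4.31 to 19.9, by TCF7L2 and by RGS3, 8.71-fold higher. The orbitofrontal gyrus had 139 higher and 201 lower, led by ANO3 (6.26-fold), GDA (4.13-fold) and ST6GALNAC5 (3.94-fold), in a library whose share of olfactory receptor genes was 3.67 times (3.6 to 3.75) the median of 6 others in all counts and 1.79 times (1.75 to 1.83) in gene counts. The occipital gyrus had 133 higher and 76 lower, led by XKR5 (16.8-fold), CTC1 (15.5-fold) and FARS2 (15.4-fold), and CTC1 was also at 1136 in the medulla and 937.1 in the thalamus against 1360.0 in the occipital gyrus. The hippocampus had 26 higher and 58 lower, led by RAPGEF4 (5.81-fold), SYTL2 (4.11-fold) and C1QL3 (3.68-fold). The corpus callosum had 11 higher and 70 lower, with TCERG1L (3.62-fold) and FXYD6 (2.39-fold) beside NEUROD6. The postcentral gyrus had 10 higher and 15 lower, with STAC2 (2.59-fold) and HAPLN4 (2.56-fold) beside SPARCL1. In simulated data with 20% spread between libraries, the rule set apart 182 of 8684 unchanged genes in the thalamus and 53 of 8663 in the cerebellum. The 84 genes of the hippocampus, 81 of the corpus callosum and 25 of the postcentral gyrus lie below the former, and cannot be told from such spread. The 209 of the occipital gyrus lie little above it. Only these 2 depths were examined, and the thalamus library had the fewest gene counts. The number to be set apart by such spread in the deeper hippocampus and postcentral libraries is therefore not known.

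The counts of genes set apart follow the scale and the libraries compared. On the all-count scale the share of genes set apart that were higher went from 40.6% to 96.9% in the cerebellum, 40.9% to 99.6% in the orbitofrontal gyrus, 40% to 90.9% in the postcentral gyrus, 45% to 0.348% in the thalamus, 55.4% to 2.31% in the medulla, 63.6% to 24.2% in the occipital gyrus and 13.6% to 0% in the corpus callosum. The median of all genes shifted by 1.33 log2 in the cerebellum, 1.13 in the orbitofrontal gyrus, -1.14 in the thalamus, -0.955 in the medulla, 0.414 in the postcentral gyrus, 0.425 in the hippocampus, -0.422 in the occipital gyrus and -0.454 in the corpus callosum. In the medulla the share was 42.7% with trimmed means and 44.6% with median-of-ratios factors, and the median of all genes shifted by -0.109 log2 with the former. With cerebellum counts thinned to the depth of the others, an alternative chosen after seeing the data, 451 genes were higher and 834 lower in the cerebellum, of 5697. Without the hippocampus library 527 genes were set apart in the orbitofrontal gyrus in place of 340, and without the medulla library 798 in the thalamus in place of 493. The 25 of the postcentral gyrus became 66, 48, 61 and 50 without the orbitofrontal, hippocampus, occipital and corpus callosum libraries, the 84 of the hippocampus became 232, 138 and 156 without the orbitofrontal, postcentral and corpus callosum libraries, and the 81 of the corpus callosum 138 and 135 without the orbitofrontal and hippocampus libraries.

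Among 108 miRNAs, 20 were set apart higher and 34 lower in the cerebellum, and at most 11 in any other region. With less weight on the depth of that library fewer were higher: 3 were higher and 28 lower of 57 with its counts thinned, and 3 and 41 of 92 with a filter on mean CPM, alternatives chosen after seeing the data. The miRNA miR-135b-5p (MIR135B, chromosome 1, 205448302 to 205448398) was at 3857 CPM (3658 to 4064) in the cerebellum, 749.9 in the medulla, 298.7 in the thalamus and 0 to 64.2 elsewhere. There miR-455-3p was at 1872 (1734 to 2018) against 0 to 373.4, miR-218-5p 6.64-fold higher, and the neuronal miR-124-3p 2.42-fold higher, while miR-1260a and miR-1260b, whose sequences resemble tRNA fragments, were 146-fold and 119-fold lower. In the medulla miR-204-5p (6.15-fold), miR-135a-5p (5.39-fold) and miR-100-5p (2.27-fold) were higher, and miR-7-5p (7.83-fold), miR-128-3p (3.01-fold) and miR-124-3p (2.88-fold) were lower. In the orbitofrontal gyrus 5 were higher and 6 lower, with miR-7-5p (a copy at MIR7-1, chromosome 9, 83969748 to 83969857) 3.6-fold, miR-299-5p 3.49-fold and miR-137-3p 2.53-fold higher, and miR-21-5p 4.2-fold and miR-598-3p 3.81-fold lower. The thalamus had 3 higher, miR-1260b (5.97-fold), miR-1260a (4.91-fold) and miR-4270 (3.39-fold), and the occipital gyrus 3, miR-4454 (12.2-fold), miR-30b-5p (2.54-fold) and miR-451a of red cells (2.12-fold), with miR-485-5p 2.76-fold lower. The corpus callosum had 3 higher, miR-330-3p (2.32-fold), miR-145-5p (2.08-fold) and miR-181a-5p (2.05-fold), and 4 lower, among them miR-377-3p on 1 count (83.4, 2.11 to 464.8) and miR-101-3p on 2 counts (166.9, 20.2 to 602.8). The hippocampus had 3 lower, among them miR-30a-3p (4.59-fold) and miR-484 (3.38-fold), and the postcentral gyrus 2, miR-195-5p (2.02-fold) and miR-455-3p, which had 0 counts and an upper limit of 168.3. In simulated data with 20% spread between libraries, the rule set apart 18 of 76 unchanged miRNAs in the thalamus and 6 of 75 in the cerebellum. The counts of at most 11 outside the cerebellum lie below the former, and as counts cannot be told from such spread. Only the thalamus and cerebellum libraries were examined in the simulation. Its false calls were not split by size, so it does not judge single miRNAs with large ratios.

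Of the 10 most abundant miRNAs, let-7a-5p ranged from 118600 CPM in the occipital gyrus to 232600 in the cerebellum, and miR-7-5p from 10920 in the medulla to 216900 in the orbitofrontal gyrus. The others were miR-125b-5p and miR-23b-3p, set apart lower in the cerebellum by 3.36-fold and 2.89-fold but log2 0.754 and 0.756 higher on the all-count scale, let-7f-5p, set apart higher there by 2.04-fold, miR-124-3p, let-7b-5p, let-7c-5p, let-7g-5p and miR-9-5p. By trimmed means and median-of-ratios factors the share of miRNAs set apart that were higher went from 45.5% to 62.5% and 66.7% in the orbitofrontal gyrus, from 75% to 60% and 50% in the occipital gyrus and from 50% to 28.6% and 37.5% in the medulla. On the all-count scale it became 6.25% in the orbitofrontal gyrus, 100% in the occipital gyrus, 86.7% in the cerebellum (from 37%), 50% in the hippocampus (from 0%) and 0% in the thalamus (from 100%) and corpus callosum (from 42.9%). The median of all miRNAs shifted by 2.15 log2 in the cerebellum, 0.916 in the occipital gyrus, 0.306 in the hippocampus, 0.278 in the medulla, -0.267 in the postcentral gyrus, -0.664 in the corpus callosum and -0.668 in the thalamus. With trimmed means it shifted by 0.222, -0.2, -0.181 and 0.23 in the orbitofrontal gyrus, thalamus, medulla and cerebellum, and with median-of-ratios factors by 0.363, -0.245, -0.119 and 0.392. Without the cerebellum library the counts of miRNAs set apart were 22 in the orbitofrontal gyrus, 13 in the medulla, 7 in the hippocampus and 4 in the corpus callosum. Without the orbitofrontal library they were 5 in the hippocampus, 6 in the thalamus and 4 in the corpus callosum. The 3 of the thalamus became 6, 5, 11 and 8 without the postcentral, hippocampus, medulla and corpus callosum libraries, the 4 of the occipital gyrus 7 without the thalamus library, and the 2 of the postcentral gyrus 1 without the thalamus or occipital library.

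The oligodendrocyte miRNAs were low in the cerebellum, with all 4 measured members set apart lower and a median log2 ratio of -2.34 (-2.44 to -2.23), which on the all-count scale was 0.0584. That median lay at percentile 10.84 of random lists, since many abundant miRNAs were lower there. The miRNAs miR-219a-2-3p and miR-338-3p, which drive oligodendrocyte maturation, were 23.1-fold and 4.69-fold lower, the latter turning to a log2 ratio of 0.068 on the all-count scale. In the orbitofrontal gyrus the list was at -1.30, and elsewhere between -0.16 and 0.51, with the signs of the thalamus and corpus callosum changing on the all-count scale. The 10 members of the let-7 family, which is linked to differentiated cells, were at 0.71 (0.68 to 0.85, percentile 99.84) in the cerebellum, with let-7i-5p and let-7f-5p set apart higher and let-7d-3p lower (log2 0.793 higher on the all-count scale), and between -0.307 and 0.117 elsewhere, 5 of these values changing sign on the all-count scale. The imprinted 14q32 cluster was at 1.19 (percentile 84.73) in the cerebellum, with 5 of 10 members set apart higher, such as miR-376c-3p (4.42-fold) and miR-379-5p (4.04-fold), and between -0.512 and 0.34 elsewhere, 4 of these values changing sign on the all-count scale. The cerebellum value was 0.41 with a mean count of 10 and 0.138 with no count filter. Only 10 of 62 members reached a mean count of 50, and the cerebellum weighs most in that mean, as for miR-379-5p with 423 counts there and 3 to 8 elsewhere. Vascular miRNAs were at -2.08 (percentile 14.98) in the cerebellum, with 4 of 5 set apart lower, such as miR-139-5p (40.2-fold) and miR-126-3p (3.3-fold, but log2 0.431 higher on the all-count scale), and between -0.542 and 0.44 elsewhere, with 3 changing sign on the all-count scale, and the near-zero values of hippocampus and medulla changing sign with trimmed means. The 3 measured microglia and leukocyte miRNAs were at -1.99 in the orbitofrontal gyrus, 0.69 in the medulla and -1.55 in the cerebellum, the last turning to 1.01 on the all-count scale. The only measured member of the ciliated and choroid plexus list, miR-204-5p, was at 2.62 in the medulla, 2.27 in the thalamus and 0.69 in the cerebellum.

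Among miRNAs of rodent surveys, the 3 measured names reported as high in cerebellum had a median of 1.60 there and 1.22 in the occipital gyrus. Of these, miR-195-5p and miR-497-5p held 853 and 553 counts in the cerebellum and 7 to 27 and 3 to 31 elsewhere, so they passed the count filter through that library. The cerebellum median rests on these 2 names, at 1.6 and 1.64, since the remaining member was below the median of the other libraries there. The 4 reported as low in cerebellum had a median of 0.136 there and -1.09 in the medulla. That cerebellum value was -0.0186 with a mean count of 10, -0.68 with no count filter, -0.769 as a mean over members and -0.233 against the gyri, so its sign is not settled, and its member miR-221-3p was set apart lower there, 19.3-fold. Neuronal miRNAs lay between -0.222 and 0.096 over 10 members, with the signs of the orbitofrontal gyrus, thalamus, occipital gyrus and medulla changing on the all-count scale. In the cerebellum 3 were set apart higher and 2 lower. Astrocyte miRNAs lay between -0.591 in the cerebellum, 1.37 on the all-count scale, and 0.405 in the occipital gyrus, the thalamus value of 0.37 turning to -0.436 as well. The miR-17/92 family lay between -0.945 in the cerebellum, 1.23 on the all-count scale, and 0.68 in the medulla. Its signs in the postcentral gyrus, thalamus and corpus callosum also changed on that scale. The erythroid list was measured through miR-451a alone, at 1.08 in the occipital gyrus, 0.955 in the hippocampus and 0.899 in the medulla against -1.74 in the cerebellum, which turned to 0.817 on the all-count scale. No HOX cluster miRNA reached a mean count of 50, but together they held 121 counts in the medulla, or 5671 CPM (4706 to 6777), and 0 to 9 elsewhere, with miR-10a-5p (MIR10A, chromosome 17, 48579838 to 48579947) and miR-10b-5p among those highest in the medulla. Liver and muscle miRNAs were at 1170.0 CPM (1061 to 1287) in the cerebellum, from 425 counts of which 130 were on miR-206, and at 250.3 to 730.1 CPM elsewhere, from 3 to 18 counts.

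**Figure D4:**
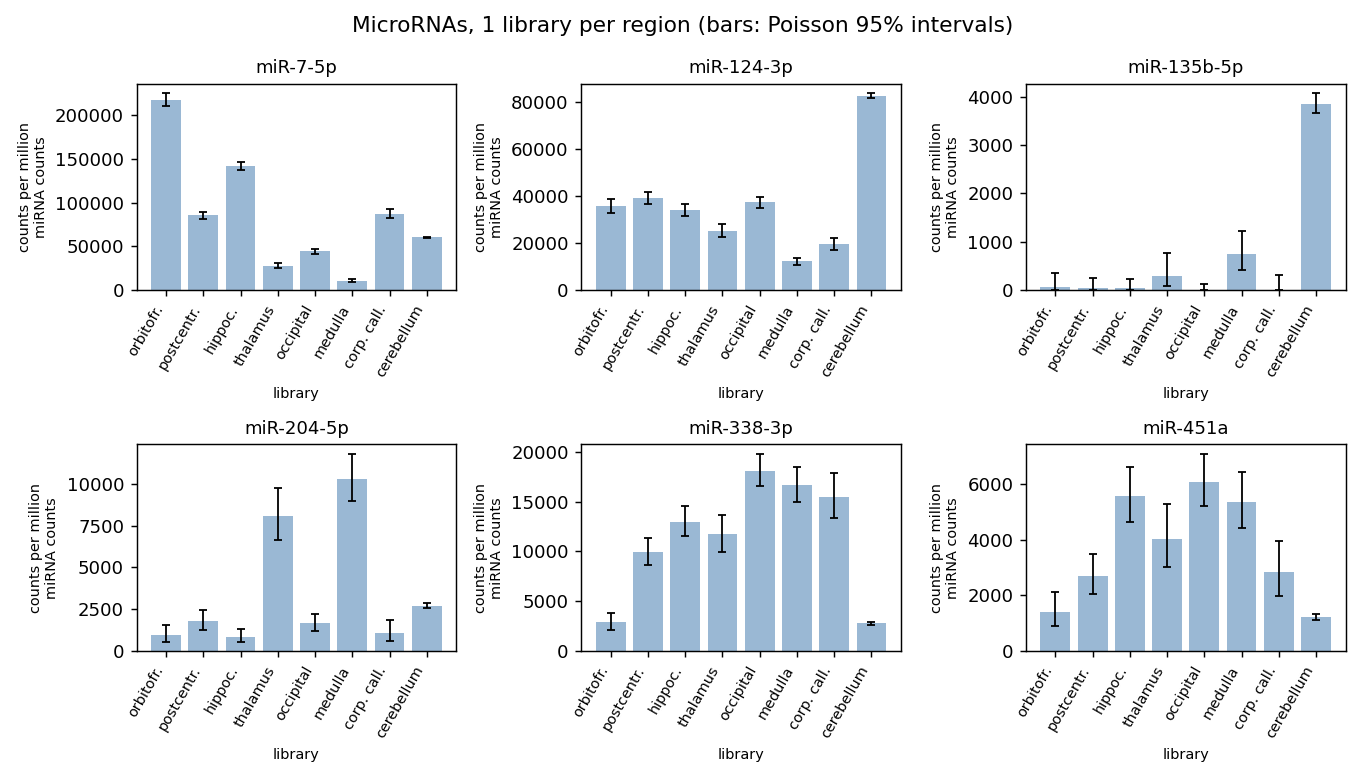
CPM of 6 miRNAs in each library, with bars for the value and whiskers for exact Poisson 95% intervals (counting error only). The miRNA miR-135b-5p is highest in the cerebellum, miR-204-5p in the medulla and thalamus and miR-7-5p in the orbitofrontal gyrus, and miR-338-3p is low in the cerebellum and orbitofrontal gyrus, though not in the cerebellum on the all-count scale.

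Among lncRNAs, CDR1-AS, MALAT1 and OIP5-AS1 had the highest mean counts once clone names were passed over, a mean in which the deep cerebellum library weighs most, and each had its highest share in the cerebellum. CDR1-AS, antisense to CDR1 and the host of a circular RNA that binds miR-7, took 40.8% of lncRNA counts in the cerebellum and 2.22% in the orbitofrontal gyrus to 9.82% in the postcentral gyrus elsewhere, and circular and linear forms are not told apart by the name. MALAT1, a nuclear RNA, was at 9.94% in the cerebellum and 3.22% in the thalamus, its lowest library. OIP5-AS1 was 3.18-fold higher in the cerebellum and 3.23-fold lower in the medulla, set apart in both. On the all-count scale OIP5-AS1 was not lowest in the medulla, with 844 of 24551584 counts there against 711 of 26391100 in the thalamus. The 7 nuclear long RNAs had a median log2 ratio of 0.86 in the orbitofrontal gyrus, with 3 set apart higher, 0.43, 0.30, -0.679, -0.485, -0.712 and -0.205 in the postcentral, hippocampus, thalamus, occipital, medulla and corpus callosum libraries and -0.237 in the cerebellum. The cerebellum value turned to 1.22 on the all-count scale, 0.502 with trimmed means, 0.564 with median-of-ratios factors and 0.0163 without the orbitofrontal, postcentral or hippocampus library. With trimmed means the medulla and hippocampus values turned to 0.12 and -0.061. Of 873 lncRNAs, 43 were set apart higher and 295 lower in the cerebellum, 9 and 228 in the medulla and 165 and 5 in the orbitofrontal gyrus. Those calls rest on shares of a class in which CDR1-AS alone took 40.8% in the cerebellum. CTD-2651B20.6 and CTD-2651B20.7 took 23.6% and 23.7% of it in the medulla and 0.144% and 0.147% in the orbitofrontal gyrus. The trimmed-mean factors for lncRNAs were 0.635 in the medulla and 1.5 in the orbitofrontal gyrus, so the direction of the calls there also depends on these names.

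The cerebellum was the library least like the others in both classes. Its median Spearman rho with the other 7 was 0.739 across genes and 0.489 across miRNAs, where genes are not independent replicates, and the medians of the other regions ran from 0.828 (medulla) to 0.937 (postcentral gyrus) across genes and 0.82 (orbitofrontal gyrus) to 0.926 (thalamus) across miRNAs. The highest value across genes, 0.966, joined the corpus callosum and hippocampus libraries, and thalamus and medulla had 0.913. The first principal component held 42.9% of the variance across genes and 63.8% across miRNAs. The cerebellum lay farthest out on it in both classes, and across genes thalamus and medulla lay on its side. With a mean count of at least 500, the cerebellum's median rho was 0.438 across genes and 0.689 across miRNAs, and for miRNAs that of the medulla, 0.688, was as low. The deep cerebellum library weighs most in the mean count that features had to reach. An example is miR-455-3p, with 680 counts there and 0 to 6 elsewhere. Similarity was not computed with that library thinned.

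Oligodendrocyte miRNAs and oligodendrocyte mRNA fragments varied together over the 8 libraries on the CPM scale. Pearson's r between their list means was 0.897 (two-sided exact permutation p = 0.00141, adjusted 0.00212 over 3 relations) and rho was 0.881 (exact permutation p = 0.00724, adjusted 0.0109). Both were lowest in the cerebellum and orbitofrontal gyrus, and without those libraries r was 0.673 over 6 (exact permutation p = 0.113), so the relation rests on them. Erythroid miR-451a and haemoglobin list genes had r = 0.923 (exact permutation p = 0.00126, adjusted 0.00212) and rho = 0.905 (exact permutation p = 0.00456, adjusted 0.0109), and r = 0.931 (exact permutation p = 0.0125) without the cerebellum and orbitofrontal gyrus. Neuronal miRNAs and neuronal genes had r = -0.404 (exact permutation p = 0.319, adjusted 0.319) and rho = -0.548 (exact permutation p = 0.171, adjusted 0.171), and r = -0.482 (exact permutation p = 0.357) without the occipital gyrus and corpus callosum. None of these relations was computed on the all-count scale, where the oligodendrocyte miRNA value of the cerebellum changed sign. The labels name no batch, and libraries from 1 donor would not be independent, which the labels leave open.

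**Figure D5:**
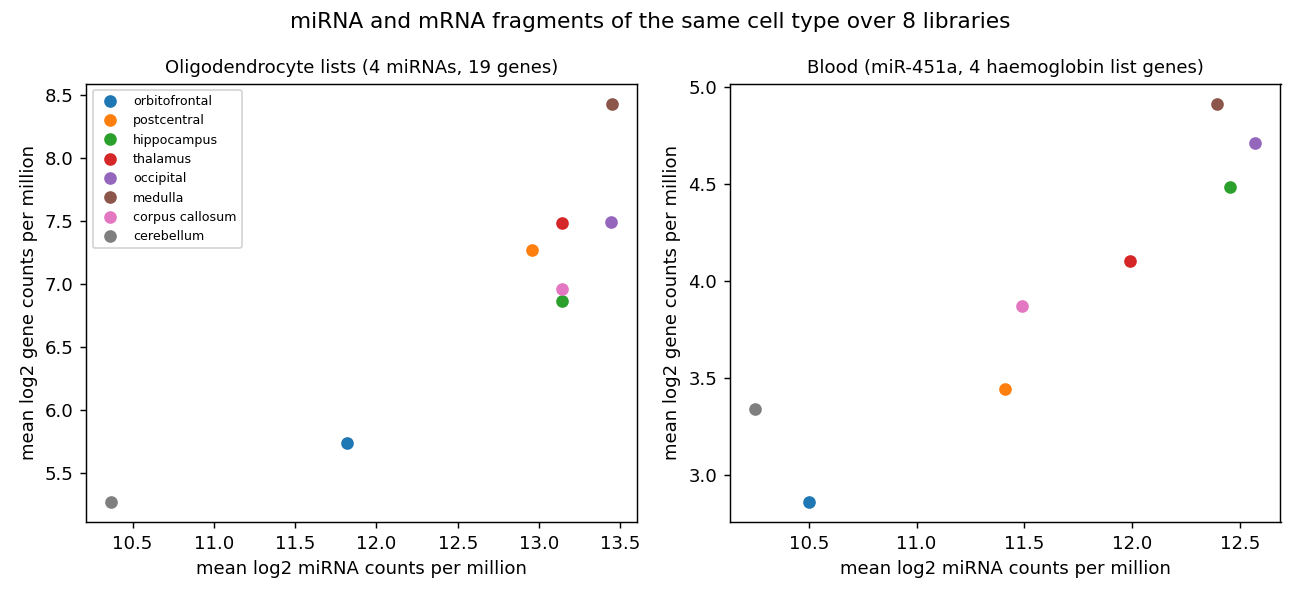
Mean log2 CPM of miRNA list members (horizontal) against mean log2 CPM of gene list members (vertical) for oligodendrocyte lists and for miR-451a with haemoglobin list genes, 1 point per library. The cerebellum and orbitofrontal gyrus lie lowest in the oligodendrocyte panel, where r is 0.897 over 8 libraries and 0.673 without these.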

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

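The tests of all explanations in this part, and the names and patterns tested, were chosen after the results had been seen. Of 15767 lncRNA names, 3 reached 10% of lncRNA counts in a library. CDR1-AS, described above, took 40.8% in the cerebellum. CTD-2651B20.6 took 23.6% in the medulla and 13.0% in the thalamus, and CTD-2651B20.7 23.7% and 13.0%.

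The library labelled corpus callosum held telencephalic neuron transcripts at 0.988 times their level in the gyri, as a share of gene counts. This argues against cortical RNA as a minor part of its gene counts. Gene counts were only 4.92% of this library, and a share cannot say how much of the piece was cortical. A minor admixture of cortical tissue was therefore not excluded. A swap with the thalamus, medulla or cerebellum library was excluded, as 0 of these 3 lacked their own markers. Carry-over from the deep cerebellum library could not have raised telencephalic neuron transcripts, which stood at 0.0647 times the gyri median in that library. Its test could thus only exclude it, and lends no weight to other explanations. Cerebellar neuron genes were at -0.308 log2 against the gyri in the library labelled corpus callosum. Oligodendrocyte genes at -0.25 log2 against the median of the gyri, within the gyri range of -1.7 to 0.259, fit grey matter in the piece or a wrong label on this library. If callosal vesicles lack telencephalic neuron transcripts, a swap with a gyrus or the hippocampus would leave 1 of these 4 libraries without them. Telencephalic neuron transcripts stood at 1.11, 1.0, 1.06 and 0.926 times the gyri median in the orbitofrontal, postcentral, hippocampus and occipital libraries. These values argue against such a swap only under that condition, which was not tested. As 2 of these 4 libraries also held more oligodendrocyte fragments than this one, the swap could not be decided. RNA from callosal axons of cortical neurons was not tested.

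The names miR-1260a, miR-1260b, miR-4454, CTD-2651B20.6 and CTD-2651B20.7 followed the tRNA share with r = 0.987 (two-sided exact permutation p = 0.000124) over 8 libraries, and r was 0.973 without the orbitofrontal and cerebellum libraries. These names were picked because they follow tRNA, so r and p restate that choice and cannot tell whether tRNA fragments were counted under them. Reads would be needed to decide.

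Introns with intergenic sequence were high in the orbitofrontal and cerebellum libraries. For the orbitofrontal library the share of 383 olfactory receptor genes, silent in most of the brain, was 3.67 times the median of 6 others in all counts but 1.79 times in gene counts, so genomic DNA stays open. In the cerebellum library these ratios were 1.18 and 0.494, which excludes it there. Sequencing depth was excluded for the orbitofrontal library, whose total was 0.873 times the median, but not for the cerebellum library, at 4.94 times that of the other 7. Over the 6 other libraries, log2 share and log2 depth had Pearson's r = 0.254 (two-sided exact permutation p = 0.628). None of these 6 was as deep as the cerebellum library, so this cannot decide. More nuclear RNA in these libraries, at a ratio of 1.69, could not be told, since only some of the 4 nuclear RNAs were above the median.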

How the results depend on the processing

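The list of main results, the thinned cerebellum and the filter on mean CPM were chosen after a first run of the alternatives had been seen, and the other settings before the data were examined. Of the settings applied to main results, 403 left the value near the main one, 206 moved it and 4 reversed it, and for the other results these counts were 2353, 430 and 20. A list value counts as reversed there only if it was a main result or lay outside the central 95% of random lists. Over all 208 list values, whatever their size, 71 changed sign on the all-count scale, 32 with no count filter, 16 with median-of-ratios factors, 12 with trimmed means, 40 without at least 1 of the libraries, and 111 under at least 1 setting. No paired analysis was possible because each region had 1 library and the labels do not say which libraries share a donor. The cause of the differences below was not tested, except where a setting removes or adds features by its construction.

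Counts of features set apart are given in the order orbitofrontal, postcentral, hippocampus, thalamus, occipital, medulla, corpus callosum and cerebellum. The main counts were 11, 2, 3, 3, 4, 6, 7 and 54 for miRNAs and 340, 25, 84, 493, 209, 891, 81 and 1807 for genes. With a mean count of at least 10 (of 208 miRNAs and 13631 genes) the miRNA counts were 25, 6, 8, 10, 10, 22, 16 and 87 and the gene counts 707, 169, 340, 1072, 797, 1770, 292 and 3328. In the cerebellum, 27 of these miRNAs were higher and 60 lower. With no count filter (of 1224 miRNAs and 20027 genes) the miRNA counts were 125, 91, 27, 93, 33, 100, 100 and 928 and the gene counts 1022, 374, 498, 2212, 2157, 2513, 573 and 5676. In the cerebellum, 37 of these miRNAs were higher and 891 lower. With a 2-fold distance from the nearest library the miRNA counts were 0, 0, 0, 0, 1, 2, 0 and 31 and the gene counts 21, 1, 1, 61, 30, 103, 8 and 735. With a ratio of at least 4-fold the miRNA counts were 1, 1, 1, 2, 1, 3, 1 and 24 and the gene counts 12, 1, 2, 74, 47, 138, 4 and 501. With the cerebellum thinned, chosen after seeing the data (of 57 miRNAs and 5697 genes) the miRNA counts were 5, 0, 1, 3, 2, 5, 3 and 31 and the gene counts 212, 7, 37, 299, 115, 590, 16 and 1285. In the cerebellum, 3 of these miRNAs were higher and 28 lower. With the filter on mean CPM, chosen after seeing the data (of 92 miRNAs and 4333 genes) the miRNA counts were 8, 0, 2, 3, 5, 7, 7 and 44 and the gene counts 154, 3, 24, 213, 87, 479, 9 and 925. In the cerebellum, 3 of these miRNAs were higher and 41 lower. On the all-count scale the miRNA counts were 16, 4, 4, 7, 26, 5, 23 and 75 and the gene counts 2435, 33, 28, 3448, 265, 1686, 250 and 4784. With trimmed means the miRNA counts were 8, 1, 2, 2, 5, 7, 8 and 57 and the gene counts 322, 27, 88, 501, 209, 848, 72 and 1795. With median-of-ratios factors the miRNA counts were 9, 1, 3, 2, 6, 8, 6 and 58 and the gene counts 328, 27, 88, 495, 208, 849, 71 and 1798. With 2 added to each count the miRNA counts were 10, 1, 3, 3, 4, 6, 6 and 51 and the gene counts 323, 22, 82, 445, 180, 835, 55 and 1819.

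With trimmed means, the list values were oligodendrocyte miRNAs -2.08 in the cerebellum library (main -2.34) and let-7 family 0.94 in the cerebellum library (main 0.71). Beside these were oligodendrocyte genes 1.42 in the medulla library (main 1.5). With median-of-ratios factors, the list values were oligodendrocyte miRNAs -1.94 in the cerebellum library (main -2.34) and let-7 family 1.07 in the cerebellum library (main 0.71). On the all-count scale, the list values were oligodendrocyte miRNAs 0.0584 in the cerebellum library (main -2.34, reversed) and let-7 family 2.75 in the cerebellum library (main 0.71). Beside these were oligodendrocyte genes -0.526 in the orbitofrontal library (main -1.46), 0.254 in the hippocampus library (main -0.428, reversed), -0.63 in the thalamus library (main 0.406, reversed), 0.777 in the medulla library (main 1.5), -0.415 in the corpus callosum library (main -0.224), -1.03 in the cerebellum library (main -2.33) and neuronal genes 0.671 in the cerebellum library (main -0.679, reversed). Further values were telencephalic neuron genes -4.17 in the thalamus library (main -3.21), -4.11 in the medulla library (main -3.2), -2.7 in the cerebellum library (main -3.88) and cerebellar neuron genes -0.226 in the medulla library (main 0.606, reversed), 5.56 in the cerebellum library (main 4.36). Then came thalamic genes 1.45 in the thalamus library (main 2.63) and astrocyte genes 0.412 in the orbitofrontal library (main -0.776, reversed), -0.534 in the thalamus library (main 0.768, reversed), -0.204 in the occipital library (main 0.325, reversed), 0.132 in the medulla library (main 1.25), 0.336 in the cerebellum library (main -0.964, reversed). They were also microglia genes 0.345 in the orbitofrontal library (main -0.715, reversed), -0.459 in the thalamus library (main 0.762, reversed), 0.853 in the medulla library (main 1.64), -0.126 in the cerebellum library (main -1.45) and vascular genes -0.168 in the corpus callosum library (main 0.363, reversed), 0.168 in the cerebellum library (main -1.05, reversed). Beside these were haemoglobin genes 0.255 in the cerebellum library (main -1.27, reversed). With a mean count of at least 10, the list values were oligodendrocyte miRNAs -2.45 in the cerebellum library (main -2.34). With no count filter, the list values were oligodendrocyte miRNAs -2.45 in the cerebellum library (main -2.34) and choroid plexus genes -0.00234 in the cerebellum library (main 1.64, reversed). Beside these were liver genes 1.22 in the occipital library (main -2.2, reversed), -0.715 in the cerebellum library (main 2.16, reversed). With the mean over members, the list values were oligodendrocyte miRNAs -2.8 in the cerebellum library (main -2.34) and let-7 family 0.617 in the cerebellum library (main 0.71). Beside these were oligodendrocyte genes 1.42 in the medulla library (main 1.5), -1.93 in the cerebellum library (main -2.33) and telencephalic neuron genes -3.42 in the cerebellum library (main -3.88). Further values were thalamic genes 1.39 in the thalamus library (main 2.63). Against the 3 gyri, the list values were oligodendrocyte miRNAs -1.93 in the cerebellum library (main -2.34) and oligodendrocyte genes 1.26 in the medulla library (main 1.5). Beside these were telencephalic neuron genes -0.0181 in the corpus callosum library (main 0.257, reversed) and thalamic genes 2.28 in the thalamus library (main 2.63). Further values were astrocyte genes 0.944 in the medulla library (main 1.25) and microglia genes -0.95 in the cerebellum library (main -1.45). Then came haemoglobin genes 0.206 in the corpus callosum library (main -0.894, reversed).

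Without rRNA counts, the share in the library highest in the main setting over that in the library lowest there was 0.976 for mitochondrial RNA (main 1.56, reversed), 76.0 for tRNA (main 39.9), 3.42 for 7S RNA (main 1.76), 1.32 for U RNA (main 2.6), 1.52 for snoRNA and scaRNA (main 4.79), 34.2 for Y RNA (main 18.0), 2.1 for introns and intergenic (main 6.39), 1.4 for gene symbols (main 4.4), 1.64 for miRNA hairpin (main 5.17), 1.15 for lncRNA (main 3.63), 1.87 for miRNA (main 5.9), 1.4 for transcript identifiers (main 4.41). Without the most abundant feature, the share in the library highest in the main setting over that in the library lowest there was 1.32 for rRNA (main 1.33), 4.43 for gene symbols (main 4.4), 2.49 for lncRNA (main 3.63). Over features with a mean count of at least 10, the share in the library highest in the main setting over that in the library lowest there was 1.32 for rRNA (main 1.33), 6.42 for introns and intergenic (main 6.39), 4.44 for gene symbols (main 4.4), 5.69 for miRNA hairpin (main 5.17), 3.76 for lncRNA (main 3.63), 4.71 for transcript identifiers (main 4.41). Over all 8 libraries, the highest over the lowest share without rRNA was 2.17 for mitochondrial RNA, 76.0 for tRNA, 3.55 for 7S RNA, 3.85 for U RNA, 2.29 for snoRNA and scaRNA, 12.5 for vault RNA, 34.2 for Y RNA, 2.1 for introns and intergenic, 2.14 for gene symbols, 2.77 for miRNA hairpin, 1.25 for lncRNA, 4.13 for miRNA, 1.78 for transcript identifiers. With the setting all-count scale, the number of list medians at least 2-fold from the others (miRNA lists by region) was 31 (main 15). With the setting no count filter, the number of list medians at least 2-fold from the others (miRNA lists by region) was 8 (main 15). With the setting mean count of at least 500, the similarity of the cerebellum to the other libraries was 0.689 across miRNAs (main 0.489). With the setting mean count of at least 500, the similarity of the cerebellum to the other libraries was 0.438 across genes (main 0.739).

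With 1 library left out in turn, the lowest and highest values were as follows. For miRNAs set apart they were 10 (without corpus callosum) and 22 (without cerebellum) in the orbitofrontal library, 1 (without thalamus) and 3 (without orbitofrontal) in the postcentral library, 3 (without postcentral) and 7 (without cerebellum) in the hippocampus library, 4 (without occipital) and 11 (without medulla) in the thalamus library, 4 (without medulla) and 7 (without thalamus) in the occipital library, 5 (without orbitofrontal) and 13 (without cerebellum) in the medulla library, 4 (without orbitofrontal) and 9 (without medulla) in the corpus callosum library. For protein-coding genes set apart they were 248 (without medulla) and 527 (without hippocampus) in the orbitofrontal library, 27 (without thalamus) and 66 (without orbitofrontal) in the postcentral library, 61 (without medulla) and 232 (without orbitofrontal) in the hippocampus library, 455 (without orbitofrontal) and 798 (without medulla) in the thalamus library, 64 (without medulla) and 138 (without orbitofrontal) in the corpus callosum library. For oligodendrocyte genes they were -0.0087 (without cerebellum) and 0.327 (without thalamus) in the postcentral library, 1.41 (without cerebellum) and 1.64 (without postcentral) in the medulla library, -0.35 (without orbitofrontal) and -0.0856 (without occipital) in the corpus callosum library, -2.45 (without orbitofrontal) and -2.21 (without thalamus) in the cerebellum library. For telencephalic neuron genes they were 0.0843 (without thalamus) and 1.09 (without orbitofrontal) in the corpus callosum library. For cerebellar neuron genes they were -0.639 (without hippocampus) and 0.0355 (without cerebellum) in the postcentral library. For thalamic genes they were 2.59 (without postcentral) and 2.97 (without medulla) in the thalamus library. For astrocyte genes they were -0.000893 (without orbitofrontal) and 0.378 (without thalamus) in the occipital library. For microglia genes they were -1.57 (without orbitofrontal) and -1.17 (without thalamus) in the cerebellum library. Values of -0.0087, 0.0355 and -0.000893 in that series have the sign opposite to the main value. Of the 40 list values that changed sign without 1 library, the others were within the central 95% of random lists, such as telencephalic neuron genes (-0.111 to 0.439) and choroid plexus genes (0.342 to -0.0252) in the occipital library, and none had a main value above 0.375 log2 in size.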

Other observations

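The relation tested in this part and the features named in it were chosen after their values had been seen.

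CDR1-AS carries many binding sites for miR-7, and both differed widely between regions. Over 8 libraries the relation of CDR1-AS and miR-7-5p had r = 0.00869 (two-sided exact permutation p = 0.982), while r was 0.651 without the cerebellum and orbitofrontal libraries and 0.598 (p = 0.113) on the all-count scale, so the hypothesis that their levels go together could not be decided. More libraries per region and reads over the circular junction would test it.

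In the occipital gyrus POLR1A was at 19640 CPM, PTPN18 at 3538 and OPN1MW at 334.2, each set apart higher, and CTC1, XKR5 and FARS2 were set apart higher there as well. POLR1A and PTPN18 were next highest in the medulla, at 6774 and 1225, and lowest in the cerebellum, at 97.1 and 30.6. In the medulla the 8 HOX cluster miRNAs held 121 counts, against 0 to 9 elsewhere, with 4 of them at their highest CPM there.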
